A study of Glycine max with 6 samples.

How the data were processed

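RNA of 2 leaf cell layers of mature soybean leaves was measured on 6 one-colour Affymetrix soybean arrays, 3 for paraveinal mesophyll (PVM) and 3 for palisade parenchyma (PP). Per the labels' protocols, untreated plants were raised in growth chambers. Leaves were fixed in ethanol and acetic acid and embedded in paraffin, and cells were cut out of sections by laser microdissection. Cells of each sample were pooled for RNA extraction, and the RNA was put through a whole-transcriptome amplification before biotin labelling. Per the labels, the replicates of each layer are biological. Whether a PVM and a PP sample came from the same plant is not given in the sources used here. Groups were taken from the sample titles, which write PP1 for the palisade samples, shortened to PP here. The free-text description of the PP samples names paraveinal cells, whereas their titles, source names and cell type entries name palisade cells, and the latter were followed.

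The deposited values are linear probe-set intensities, 1 per probe set and array, and none is below 0. The program that made them, its summarisation method and its scaling target are not given in the sources used here. The 2% trimmed mean was the same on each array, 125, so the intensities appear to have been scaled by the authors to a common mean. Array medians still differed, from 7.08 to 12.9. The values were therefore taken as log2(intensity + 16) and quantile-normalized between arrays over all 61170 probe sets. Differences are on this scale, which understates the change of dim probe sets. Means and SDs given as intensities are the deposited values before quantile normalization.

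The array holds 37593 soybean probe sets. For each array, background was set at the 95th percentile of the 23350 probe sets that the array carries for other organisms. A soybean probe set was tested if it lay above background on at least 3 of the 6 arrays, which 25314 did. Control, ribosomal RNA and pathogen probe sets were not tested. The share of soybean probe sets above background ran from 58.4% on PP array 3 to 68.5% on PVM array 3. The number of arrays limits the precision. Where all 3 PP arrays were at or below background, the fold is a lower bound, the PVM mean against the higher of background and the measured value on each PP array, on the normalized log2 scale.

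Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, no covariates), with Benjamini-Hochberg adjustment and a threshold of 0.05. The procedure was tested on simulated data for PVM against PP, with 200 of 25314 probe sets changed. It recovered 20% of those changed by a log2 size of 2, 50% at 3, 72% at 4 and 88% at 5, with 6 false calls among 121. The simulated noise was independent between probe sets and between arrays, and the changes were added with no floor. In the data, several probe sets can measure the same gene and dim values meet a floor, so these rates may not hold there.

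Gene symbols came from the platform's probe annotation and were updated through a RefSeq gene table for the assembly Glycine_max_v4.0. Of 9047 probe sets in the annotation, 8652 matched that table. Among tested probe sets, 6675 had 1 symbol, 318 had several and were not named, and 18321 had none and are unnamed here. Of the 6675, 5558 carry only a LOC number. The deposited values come with no genome build, so the coordinates of that table, which belong to its own assembly, are not printed.

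Choices made before the data were examined were the tests, the filters, 27 gene lists and the rule for named genes. For each gene the probe set with the highest mean stood for it. The 12 genes with the largest difference in each direction past the threshold, excluding bare LOC numbers, were to be named, filled up with the smallest unadjusted p where fewer passed. Up to 4 genes with the smallest p were named per list. The lists are text patterns written for symbols and descriptions. Only symbols and synonyms were at hand, so 7 of the 27 lists had the minimum of 3 tested probe sets, 7 had fewer and 13 had none. Because of this, 13 lists of symbols were added, of which 12 could be tested. They were written after the annotation and the values of control and ribosomal probe sets had been seen, and before the other values. From the added lists, genes with an unadjusted p under 0.05 were named, a limit set after their values had been seen, and for photosynthesis the 4 with the smallest p. Lists were tested with camera (inter-gene correlation 0.01), with camera and an estimated correlation, and with fry, each adjusted over the 19 lists tested.

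Alternatives covered a replicate block, no quantile normalization, centring on the soybean median, the filter, the pseudocount, an intensity trend with a robust prior, array weights, each array left out, a stricter threshold, a minimum change and 1 probe set per gene. Added after the data were seen were averaging PP arrays 1 and 2, keeping only probe sets whose names carry no mark for shared sequence, and an estimated correlation under the other 2 scalings. Setting probe sets of a list at their bounds left the median of each tested list as it was.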

Results

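The data compare RNA of the paraveinal mesophyll (PVM), a single cell layer lying between palisade and spongy tissue in soybean leaves, with that of the palisade parenchyma (PP), the upper photosynthetic layer. Each layer was sampled 3 times by laser microdissection, and each sample was hybridised to its own array. The question the design poses is which transcripts differ in level between these layers of the same organ. Median intensity of soybean probe sets was 34.7 to 54.3 on the PVM arrays and 36.2 to 46.6 on the PP arrays. Values below are deposited intensities (mean ± SD, n = 3 arrays per layer) and log2 differences, PVM minus PP, with the standard error (SE) from limma.

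Transcripts for vegetative storage proteins, the vacuolar glycoproteins in which soybean leaves hold nitrogen, measured higher in PVM. No probe set of their list passed the threshold over all genes tested, and the list did not pass camera with an estimated correlation. All 14 tested probe sets of the list, covering VSPA, VSPB (LOC547820) and LOXB1, were higher in PVM, with a median log2 difference of 1.55 and a range of 0.64 to 2.68. VSPB had an intensity of 4401 ± 461 in PVM and 1565 ± 658 in PP on its brightest probe set, a log2 difference of 1.76 (SE 0.39). VSPA was bright in both layers, at 13888 ± 2076 in PVM and 11753 ± 2802 in PP, with a log2 difference of 0.73 (SE 0.31) that was 0.25 without quantile normalization. LOXB1 entered the list through its synonym VSP94, which names the lipoxygenase that accumulates with the storage proteins. Its probe sets differed by 1.86 to 2.68, those of VSPB by 1.76 to 2.16 and those of VSPA by 0.64 to 1.34.

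Lipoxygenases, which oxygenate polyunsaturated fatty acids, measured higher in PVM as well. Here too no probe set passed the threshold over all genes tested, nor did the list pass camera with an estimated correlation. Of 20 probe sets for 6 genes, 19 were higher in PVM, with a median log2 difference of 1.97. LOX9 measured 2484 ± 551 in PVM against 544 ± 91.3 in PP, and differed 4.59-fold after normalization. LOX7 measured 3648 ± 607 against 873 ± 488, and differed 4.85-fold after normalization. LOXB1 measured 7593 ± 701 against 2641 ± 826, and differed 3.63-fold after normalization. For LOX7 and LOXB1 these folds are larger than the ratio of the deposited means. LOC547835 (synonym LOX1.4) measured 431 ± 111 against 59.3 ± 4.50. Another probe set of that gene, the exception among the 20, had the opposite sign and was at least 1.24-fold lower in PVM, where all 3 arrays were at or below background. LOXB1 belongs to both lists.

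By camera, both lists lay above the other probe sets, with an adjusted p of 1.57e-15 for storage proteins and 4.64e-21 for lipoxygenases. Several probe sets of each list measured the same gene. With 1 probe set per gene the camera adjusted p was 0.000595 and 2.24e-09. With all probe sets and an estimated correlation, the adjusted p was 0.184 for each. By fry, which asks only whether a list moves one way, it was 0.00665 for each. No probe set of either list passed the threshold over all genes tested, while 11 of 14 and 19 of 20 passed in limma when adjusted over the list alone. With the intensity trend and robust prior, 24 of the 30 probe sets of both lists passed over all genes tested. An added list joining both had 29 of 30 probe sets higher in PVM, a median of 1.86, a camera adjusted p of 3.85e-27 and an adjusted p of 0.184 with an estimated correlation.

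**Figure D1:**
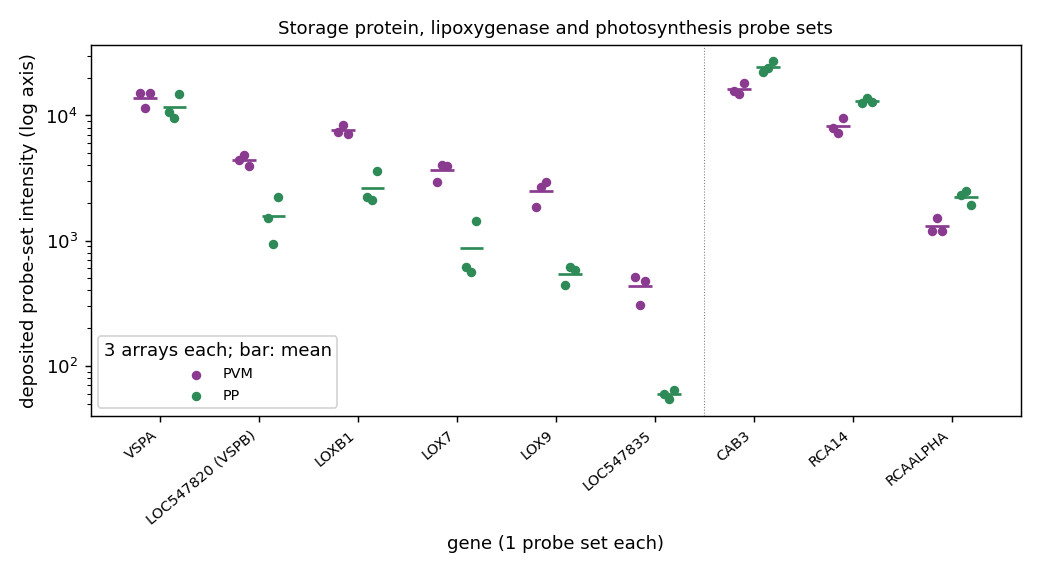
Deposited intensity (log axis) of 1 probe set for each of 9 genes, with 3 PVM and 3 PP arrays as points and the group means as bars. The 3 arrays of PVM lie above those of PP for VSPB, LOXB1, LOX7, LOX9 and LOC547835, the layers overlap for VSPA, and CAB3, RCA14 and RCAALPHA are brighter on the PP arrays on this scale, before quantile normalization.

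Photosynthesis probe sets differed by less between layers than those of the 2 lists above, and neither photosynthesis list passed the test. The light reaction list fixed beforehand held 4 tested probe sets, all of CAB3, a chlorophyll a/b-binding protein of the light-harvesting antenna. Their median log2 difference was -0.14, with a camera adjusted p of 0.677 (0.747 with an estimated correlation), and -0.22 without PP array 3. On its brightest probe set CAB3 measured 16323 ± 1824 in PVM and 24390 ± 2434 in PP, which became a log2 difference of -0.03 (SE 0.29) after normalization, and 1 of its other probe sets had the opposite sign. In the wider list added later, 21 of 27 probe sets were lower in PVM, with a median of -0.25 and a camera adjusted p of 0.146 (0.460 with an estimated correlation). That median was -0.15 without PVM array 2 and -0.13 with 1 probe set per gene. With 1 probe set per gene, the smallest p values in that list belonged to RCAALPHA, RCA11, FTRC and RCA14. RCAALPHA, a Rubisco activase, measured 1309 ± 186 in PVM and 2248 ± 283 in PP with a log2 difference of -0.68. The activases RCA11 and RCA14 differed by -0.61 and -0.26, and FTRC, a subunit of ferredoxin-thioredoxin reductase, by -0.29 (-0.16 without PP array 3). Over the other settings RCA14 ran from -0.70 to -0.22. None of the 4 passed the threshold.

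The size of this difference depended on the scaling. Without quantile normalization the median of the wider list was -0.51 with a camera adjusted p of 0.000257, and with arrays centred on the soybean median it was -0.54 with an adjusted p of 0.000958, so that the list passed the threshold under both. With an estimated correlation it passed under neither (adjusted p = 0.335 and adjusted p = 0.402). The light reaction list moved to -0.58 and -0.60 under these settings without passing. Bacterial and phage spike-in controls, which contain no leaf RNA, were also brighter on the PP arrays, by 0.52 on the deposited log2 scale.

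**Figure D2:**
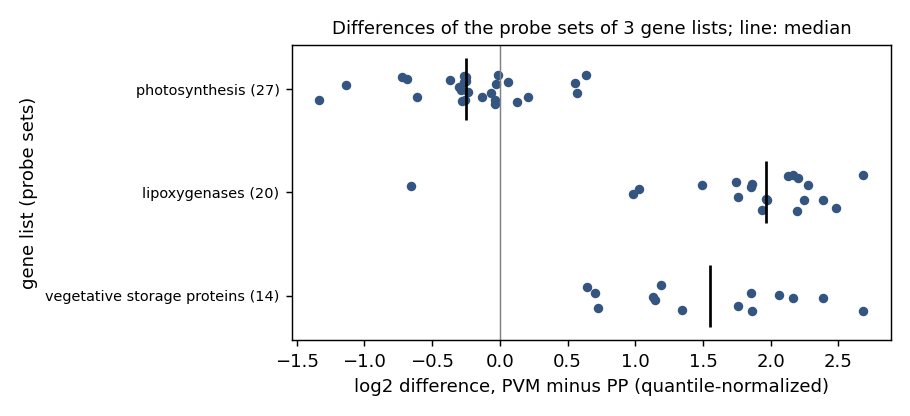
Log2 differences (PVM minus PP, quantile-normalized) of each probe set in 3 gene lists, with list medians as vertical lines. The 14 storage protein probe sets all lie above 0 (median 1.55), 19 of 20 lipoxygenase probe sets do (median 1.97), and 21 of 27 photosynthesis probe sets lie below 0 (median -0.25).

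Across all tested probe sets, 11 were higher in PVM at an adjusted p under 0.05 and 0 were higher in PP, by limma. At an unadjusted p under 0.05 the counts were 1653 and 1424. The 3 values of 1 layer lay wholly above those of the other for 2181 probe sets in favour of PVM and 2564 in favour of PP, 18.7% of those tested against 10% by chance. That 10% holds only if the 6 arrays are equally independent. PP arrays 1 and 2 correlated at 0.947, above all other pairs, so the excess over 10% cannot be judged. The smallest adjusted p on the PP side was 0.0897. The 11 probe sets have fitted log2 differences of 3.16 to 6.26. They are named here because they passed, after their values were seen.

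PR1-7, a pathogenesis-related protein 1 gene, measured 163 ± 10.6 in PVM and 3.83 ± 2.93 in PP. It was at least 5.13-fold higher in PVM (adjusted p = 0.0363), since all 3 PP arrays were at or below background. Its brighter probe set, also at or below background on the PP arrays, was at least 6.51-fold higher in PVM with a wider spread there, and did not pass. LOC100810929 had the smallest adjusted p, 0.00673, with 671 ± 93.7 in PVM and 0.707 ± 0.360 in PP, at least 20.1-fold. LOC100796662 passed on all 3 of its probe sets, with log2 differences of 5.58, 5.73 and 6.26, and LOC100794342 passed with 4.11. On each of these probe sets at least 1 PP array was at or below background, so the sizes depend on values near the floor. A probe set assigned to LOC547605 differed by 5.67, but 8 other tested probe sets of that gene ranged from -0.83 to 1.09, so that the gene's probe sets disagree. The other 4 have no gene symbol here. They differed by 4.67, 4.07, 3.82 and 3.80, and the one at 3.82 was at least 9.69-fold higher in PVM against PP arrays at or below background.

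**Figure D3:**
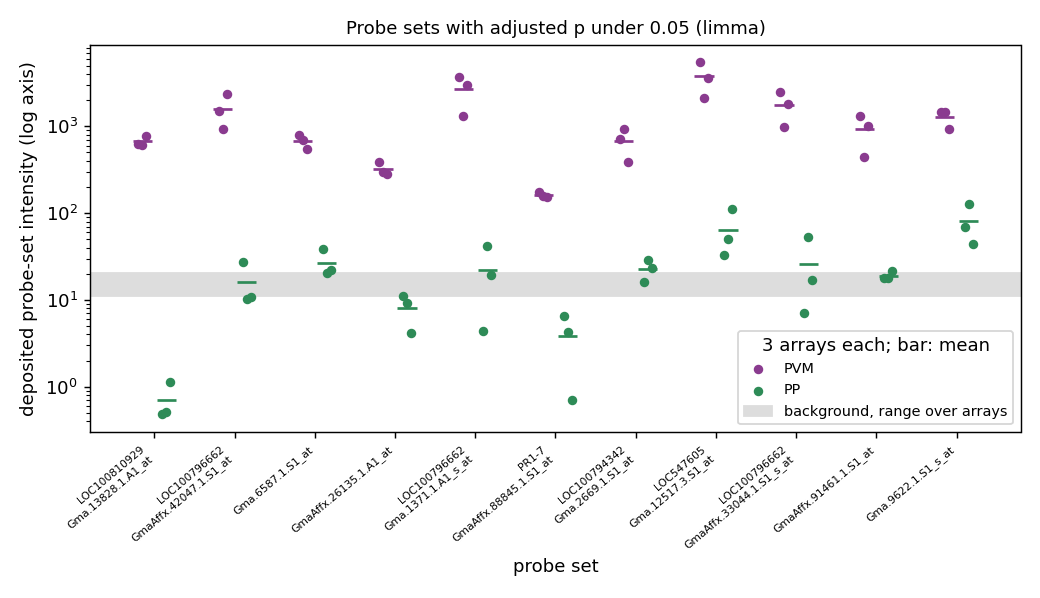
Deposited intensity (log axis) of the 11 probe sets with an adjusted p under 0.05, with 3 PVM and 3 PP arrays as points, means as bars and the range of array backgrounds in grey. Every PVM array lies above every PP array, and for LOC100810929, PR1-7 and 1 probe set with no symbol the PP arrays all lie at or below background.

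Leaving out any single array left 0 calls, except for PVM array 2, without which 3 remained. A fit with an intensity trend and robust prior called 136 probe sets higher in PVM, including all 11, and 13 higher in PP. A pseudocount of 1 gave 1 call, no filter gave 5, and 1 probe set per gene gave 4.

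None of the 24 genes named by the fixed rule passed the threshold, with adjusted p values of 0.0897 to 0.157 on the PVM side and 0.0980 to 0.268 on the PP side. All had no overlap between the layers after normalization. Since all were picked by a small unadjusted p in limma, this adds no separate evidence. On the PVM side, the transcription factor WRKY37 measured 160 ± 6.33 in PVM and 10.6 ± 8.55 in PP (log2 difference 2.79, SE 0.35). MYB145 differed by 3.47, the kinase MAPKK2 by 2.15 and the calmodulin SCAM-4 by 2.81. PP arrays 2 and 3 for WRKY37 and PP array 3 for SCAM-4 were below background, so these 2 sizes depend on values near the floor. BZIP62 was at least 3.89-fold higher in PVM, with all PP arrays at or below background. SGT2, a glycosyltransferase of soyasaponin synthesis, measured 3320 ± 710 in PVM and 504 ± 164 in PP (2.81, SE 0.38), and AMS1, an amyrin synthase by its symbol, differed by 2.83. PAP25, a purple acid phosphatase, differed by 1.82 and AG1 by 1.98. The remaining 3 were LOX9, LOX7 and LOXB1, given above. Another probe set of MAPKK2 had the opposite sign. With the intensity trend, 9 of the 24 passed.

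On the PP side, FAD6.1, a plastid omega-6 desaturase, measured 74.1 ± 21.5 in PVM and 296 ± 27.7 in PP, a log2 difference of -1.89 (SE 0.30). DGD2, a galactolipid synthase, differed by -2.45, and DXR1, an enzyme of the plastid isoprenoid pathway, by -1.51, with the opposite sign on another probe set. LHY, a morning gene of the circadian clock and the sole gene of that list, measured 107 ± 43.7 against 382 ± 87.0 (-1.85), and its second probe set differed by -0.90. GOLS, a galactinol synthase, measured 14.0 ± 5.63 against 72.3 ± 6.13 (-1.52). The sugar transporter SWEET31 differed by -1.30. WRKY15 differed by -2.16, MYB186 by -2.20, EIN4 (an ethylene receptor) by -1.98, MYB178 by -1.81, SOY69 by -1.21 and HSF-08 by -1.16. MYB178 was below background on PVM arrays 1 and 2, GOLS on PVM array 1, HSF-08 on PVM array 2 and WRKY15 on PVM array 3. The sizes for these genes depend on values near the floor.

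Of 19 gene lists tested, 6 passed with camera and 0 with an estimated correlation. Besides the 3 described, the endoplasmic reticulum folding list had all 3 probe sets higher in PVM, with a median of 1.12 (adjusted p = 0.0157 by camera, and adjusted p = 0.202 with an estimated correlation). It holds the chaperones BIP4, at 1103 ± 407 against 466 ± 70.7, and BIP2, which differed by 0.56, with overlapping arrays. BIP2 was at 0.19 without PVM array 1, 0.20 without PP array 3, 0.86 without PVM array 2 and 1.05 without PP array 1. Over the list alone, 2 of 3 probe sets passed in limma, both of BIP4. With 1 probe set for each of the 2 genes, 0 passed. Without PVM array 3 the list no longer passed by camera (adjusted p = 0.0596). An added list of protease inhibitors and vacuolar proteases had 4 of 6 probe sets higher in PVM and a median of 0.87 (adjusted p = 0.0231, and adjusted p = 0.202 with an estimated correlation). KTI-3, a Kunitz trypsin inhibitor, differed by 1.42. The call of this list was lost without PVM array 2, PVM array 3 or PP array 3 (adjusted p = 0.0609, 0.0843 and 0.0719), with 1 probe set per gene (0.107), with only probe sets that carry no mark for shared sequence (median 0.63, adjusted p = 0.0723) and with no filter, where the median was 0.11. The added list of plastid desaturases and galactolipid synthases had 10 of 12 probe sets lower in PVM and a median of -0.46 (adjusted p = 0.0120, and adjusted p = 0.218 with an estimated correlation). With 1 probe set per gene its median was -0.10 and the call was lost, as it was without PVM array 2 (adjusted p = 0.0531). The median was -0.29 without PP array 2, -0.77 without PP array 1 and -0.76 with the filter on mean intensity.

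The other lists did not pass. Among 30 aquaporin probe sets, 17 were higher in PVM and 13 lower, with a median of 0.31 (camera adjusted p = 0.0768, and adjusted p = 0.214 with an estimated correlation). By camera it passed with the filter on mean intensity (0.0172), with array weights (0.0495), without PVM array 1 (0.0404) and without PP array 3 (0.0319), and its median was 0.19 without PP array 2. The plasma membrane aquaporin PIP1-1 measured 550 ± 138 in PVM and 185 ± 63.3 in PP (1.40), PIP2-9 differed by 1.39 and SIP1-4 by -1.51. The tonoplast aquaporin TIP1-6 (LOC547794) was at least 1.41-fold higher in PVM, with all PP arrays at or below background. Sucrose and sugar transport had 1 of 4 probe sets higher in PVM (median -0.30, adjusted p = 0.215). Its median was -0.17 without PP array 3, -0.48 without PVM array 1, -0.49 without PP array 2 and -0.60 with 1 probe set per gene. SWEET34 was at -0.60 (-0.37 without PP array 3) and SWEET42 at 0.11, whose sign turned in some settings (-0.34 without PP array 2, 0.75 without PP array 3). Heat shock proteins had 4 of 15 higher (median -0.31, adjusted p = 0.259), and the median was -0.09 without PVM array 1, -0.17 without PP array 1 and -0.50 without PP array 3. In that list HSP90A1 differed by -2.10, or -1.10 without PVM array 1, HSP22.3 by -0.83, HSP17.5-E by 0.64 and HSP90-1 by -0.47, with the opposite sign on 2 of its other probe sets. Without PP array 1, HSP22.3 was at -0.42 and HSP90-1 at -0.17, and HSP22.3 was at -1.38 without PP array 3.

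Among added lists, nitrogen metabolism and transport had 21 of 36 probe sets higher in PVM and a median of 0.17 (adjusted p = 0.114, and adjusted p = 0.460 with an estimated correlation). Without PVM array 2 the median was 0.31 and the list passed by camera (adjusted p = 0.0427), and it was -0.03 without PVM array 3, 0.03 without PP array 2 and 0.35 without PP array 3. With 1 probe set per gene, the smallest p in this list belonged to a cytosolic glutamine synthetase (LOC548082, synonym GS1beta1). It measured 378 ± 59.2 in PVM and 100.5 ± 8.31 in PP, a log2 difference of 1.67 (SE 0.31). Glutamate dehydrogenase GDH1 differed by 1.56, the urease accessory gene EU3 by 1.49 and uricase UR2 by 1.13. Flavonoid and isoflavonoid genes had 19 of 33 higher (median 0.19, adjusted p = 0.114, and adjusted p = 0.493 with an estimated correlation). The list passed by camera with array weights (median 0.31, adjusted p = 0.0338), without PVM array 2 (0.37, adjusted p = 0.0251) and without PP array 3 (0.33, adjusted p = 0.0319), and its median was 0.07 without PP array 2 and 0.10 without PVM array 3. IFS2, isoflavone synthase, measured 263 ± 75.8 against 48.4 ± 33.1 (2.24), the isoflavone glucosyltransferase IF7GT differed by 1.92 and F3H by 1.11. CHS8 was at least 1.24-fold higher in PVM, its PP arrays being at or below background. Sugar transport and carbohydrate genes had 8 of 24 higher (median -0.26, adjusted p = 0.450, and a median of -0.04 without PVM array 3), with the beta-amylase LOC547931 at 1.25 beside GOLS and SWEET31. The sucrose synthase SS was at least 2.53-fold higher in PVM, with PP arrays at or below background. Antioxidant enzymes had 8 of 21 higher with a median of -0.09, while the mean (0.13) and the camera direction were positive (adjusted p = 0.752). The median was -0.19 without PP array 1 and 0.01 without PP array 3. DHAR4 differed by 1.99, PRX2 by 2.03, PRX2B by 1.55 and SOD1 by 1.05 (0.67 without PVM array 1). The lowest probe set of this list was at -1.29. In limma adjusted over the list alone, 2 probe sets passed as higher in PVM and 1 as lower. Jasmonate and oxylipin genes had 8 of 14 higher (median 0.07, adjusted p = 0.253, and a median of 0.68 with 1 probe set per gene, adjusted p = 0.0788), with the allene oxide cyclase AOC6 at 1.62, or 1.01 without PVM array 3. The median of this list was 0.07 to 0.23 with single arrays left out. Secretory folding genes had 10 of 13 higher (median 0.31, adjusted p = 0.101, and adjusted p = 0.460 with an estimated correlation). Without PP array 1 the median was 0.51 and the list passed by camera (adjusted p = 0.0319), and without PP array 3 it was 0.13. Phosphoenolpyruvate carboxylases and their kinases had 8 of 8 higher by little (median 0.08, adjusted p = 0.585, and a median of 0.30 without PVM array 2 and -0.02 without PVM array 3). Of 6 probe sets for seed storage and maturation genes, 3 were higher (median -0.11, adjusted p = 0.587, and a median of -0.29 without PVM array 3 and 0.08 without PP array 3).

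Lists with fewer than 3 tested probe sets have values only. The nitrate transporter NRT1-3 measured 1303 ± 375 in PVM and 743 ± 118 in PP. CYSTATIN differed by 0.63, an expansin (LOC100499976) by 1.36 (0.88 without PP array 2), and the jasmonate repressor JAZ1 (LOC100778559) by -0.13 (-0.39 without PP array 1, 0.10 without PP array 3). NOD33, from the nodule list, differed by 1.81.

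Markers of other leaf cell types were few. Of 11 probe sets for sieve element occlusion genes of the phloem, 1 (SEOE) was above background on enough arrays and differed by -0.83, or -0.32 without PP array 3 and -1.28 without PP array 1. SEOC, another of these genes, had a mean of 185 ± 166 on the PVM arrays and 6.86 ± 4.96 on the PP arrays and was not tested. MYB60, a guard cell gene, measured 82.8 ± 107 in PVM and 28.1 ± 25.0 in PP on 1 probe set, a log2 difference of 0.72, or 1.65 without PVM array 1 and -0.14 without PVM array 3. On its other probe set it measured 82.4 ± 93.8 and 8.05 ± 6.03, at least 2.30-fold higher in PVM with PP arrays at or below background. Of these 2 probe sets, both higher in PVM, 1 passed in limma when adjusted over the list alone and 0 over all genes. The lists for xylem and for epidermis had no tested probe set.

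RNA measures were compared between the layers as well. The log2 ratio of the 3′ to the 5′ actin control probe sets was 0.80 ± 0.30 in PVM and 1.52 ± 0.27 in PP (exact permutation p = 0.10, the smallest that 3 against 3 arrays can give, two-sided). The ratio of 3′ to middle GAPDH probe sets was 1.75 ± 0.27 and 1.15 ± 0.72 (exact permutation p = 0.30). It ran the other way, with overlapping layers, and PP arrays 1, 2 and 3 were at 1.45, 1.68 and 0.33. Across probe sets, which are not independent replicates, PP arrays 1 and 2 correlated at 0.947, and all other pairs of arrays at 0.811 to 0.885. PVM arrays correlated with each other at 0.847 to 0.870. With PP array 1 they correlated at 0.872, 0.856 and 0.878 (PVM arrays 1, 2 and 3). Each PVM array thus correlated more highly with PP array 1 than with any other PVM array. No 2 arrays held identical values.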

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

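The tests of array scale, shared probe sequences, phloem RNA and bright probe sets, and the averaging of PP arrays 1 and 2 as a setting, were chosen after the results they bear on had been seen in whole or part. Control probe sets outside the comparison drew attention because they differed between layers. Hybridization spike-ins (18 probe sets) were brighter on all 3 PP arrays than on any PVM array, by 0.521 on the deposited log2 scale or 1.44-fold (exact permutation p = 0.10, the smallest possible). Ribosomal RNA probe sets were brighter on the PP arrays by 0.571 (exact permutation p = 0.10). After quantile normalization these differences were 0.17 and 0.10.

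Photosynthesis probe sets were brighter on the PP arrays before normalization, in 23 of 27 cases. A candidate explanation is an array-wide shift of bright probe sets: the median photosynthesis difference on the deposited scale was 0.517, against 0.521 for spike-ins, and 638 other probe sets at least as bright had a median of 0.42. The shift is of the same size as the difference, and a layer difference smaller than the spread of spike-ins between arrays stays open, as does a true difference in RNA content between the layers.

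The 11 probe sets called higher in PVM, with 0 in PP, were set against 3 technical explanations. The array scale as the whole cause is argued against by size: the spike-in shift was 0.521, against fitted log2 differences of 3.16 to 6.26. Of the 11 probe sets, 10 were still called without quantile normalization and 11 with arrays centred on the soybean median. Under both, 0 were higher in PP. Neither scaling uses the spike-ins, and differences this large could hardly be lost to such a shift, so these counts decide little. Chance was not settled: 1 of 10 splits of the 6 arrays, the real one, gave as many calls, with 11 against a highest other of 0, and 10 splits are too few for a share under 0.05. With the closely similar PP arrays 1 and 2 averaged, the smallest difference was 3.21 and calls fell from 11 to 0. Averaging near-identical arrays leaves the folds in place by construction, so the bound set beforehand on the fold decides nothing, and leaving out either array also gave 0 calls; whether the pair counts as 2 independent samples stays open, as does a difference between the layers.

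Storage protein and lipoxygenase probe sets were higher in PVM in 29 of 30 cases. Probe sets marked as shared were not the whole cause: the 11 with no mark for shared sequence were all higher in PVM, with a median of 1.86. A missing mark does not show that a probe set reads a single gene. Signal shared between related genes without a mark therefore stays open. For chance, 1 of 10 splits, the real one, gave a median as far from 0 (1.86 against a highest other of 0.945), and 10 splits are too few for a share under 0.05. Phloem RNA in the PVM samples, which lie near veins, could not be judged, because 1 phloem probe set was above background, and SEOC was bright on PVM arrays in the mean with a spread as wide. A difference between the layers themselves stays open as a hypothesis.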

How the results depend on the processing

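The averaging of PP arrays 1 and 2, the restriction to probe sets with no shared mark and an estimated correlation under other scalings were added after the data were seen. The count of 11 probe sets higher in PVM was 10 to 13 without quantile normalization, with median centring, with the filter on mean intensity, with array weights and with a minimum log2 difference of 1. It was 5 with no filter, 1 with a pseudocount of 1, 136 with the intensity trend and robust prior, 1 at an adjusted p under 0.01, 4 with 1 probe set per gene, 0 with PP arrays 1 and 2 averaged, and 0 to 3 with single arrays left out. The count higher in PP was 13 with the intensity trend and 0 in all other settings. Stricter thresholds, fewer arrays and fewer probe sets per gene lower the count by construction; for the others the cause was not tested. With the replicate number as a block, 0 probe sets were called in either direction. The numbers do not pair the samples by the data: deviations of same-numbered arrays correlated at 0.02, 0.03 and 0.05, under the limit of 0.1, although each array deviated most alike with the other layer's array of its own number, a hint from the data and not the design. The storage protein median stayed between 1.304 and 1.857 and past the threshold, except with an estimated correlation (median 1.55, adjusted p = 0.184, 1.358 and 0.235 without quantile normalization, 1.330 and 0.231 with median centring, cause not tested). The light reaction median ranged from -0.60 to -0.10 and never passed; with 1 probe set per gene or without shared marks too few probe sets were left for a value. For 100 other lists and genes, 1408 of 1584 values kept direction and side of the threshold, 128 lost it, 30 gained it and 18 turned sign, the cause not tested. Signs turned for jasmonate and oxylipin (-0.13 with the mean filter, -0.0217 without shared marks, against 0.68 with 1 probe set per gene and 0.069 to 0.234 with single arrays left out), antioxidant enzymes (0.045 with 1 probe set per gene and without shared marks), seed genes (0.00905 with no filter, 0.0036 with weights), SWEET42 (-0.20 with PP arrays averaged) and JAZ1 (0.045 with weights). With single arrays left out, the list medians ran from -0.028 to 0.355 (nitrogen), -0.19 to 0.00519 (antioxidant), -0.021 to 0.297 (phosphoenolpyruvate carboxylase) and -0.294 to 0.075 (seed), and the genes from -0.345 to 0.747 (SWEET42), -0.393 to 0.097 (JAZ1) and -0.140 to 1.647 (MYB60). Arrays give no depth; a signal near background limits the folds given as bounds.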

Other observations

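Genes of soyasaponin synthesis, the triterpene glycosides of soybean, were at higher levels in PVM on several probe sets. CYP93E1, which oxidises the triterpene backbone, had log2 differences of 3.73, 1.34 and 1.08 on its 3 tested probe sets, so that their sizes disagree. The first, the dimmest of these, carries a mark for shared sequence and measured 1351 ± 387 in PVM and 86.6 ± 29.0 in PP. The second, the brightest and the only one with no such mark, measured 6163 ± 498 and 3190 ± 1561 (adjusted p = 0.261 by limma). A further probe set, at 10.4 ± 8.62 and 12.1 ± 11.2, was not tested. SGT2 differed by 2.81 and 2.49 on its 2 probe sets and AMS1 by 2.83. None passed the limma threshold over all probe sets, with adjusted p values of 0.0565 (CYP93E1), 0.0897 (SGT2) and 0.114 (AMS1) at the smallest. These genes were picked because of their values.

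The pattern may extend to the wider pathway, as a hypothesis. Before their values were seen, SGT3, GT4 and LOC100802222 (synonym GmCSyGT3) were set down as other pathway genes recognised by symbol or synonym. Pathway genes whose probe sets have no symbol are not covered. Of the 3 genes set down, 2 were above background on enough arrays, and their median log2 difference was 2.30. SGT3, which adds the last sugar of a soyasaponin chain, measured 699 ± 240 in PVM and 151 ± 54.9 in PP, and LOC100802222 measured 1400 ± 378 and 224 ± 92.3. Neither passed the threshold (adjusted p = 0.172 and 0.102 by limma). GT4 was not tested, with 282 ± 264 in PVM and 3.35 ± 4.59 in PP on its brightest probe set. Technical explanations were not tested for this pattern.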
